A study of Mus musculus with 53 samples.

How the data were processed

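Small RNA of microglia from 4 male and 4 female control mice and 5 male and 5 female P301S mice, all of 6 months, and messenger RNA of microglia from 35 samples in 10 groups of sex, genotype and age were analysed from the count tables deposited with the series. Per the submitters' processing notes, small RNA was ligated to adapters and size-selected on a gel, and messenger RNA was primed with oligo(dT) and sequenced from the 3′ end. The values are counts per gene and per mature microRNA, made by the authors from alignments to GRCm38 before the files were deposited; Bowtie2 is listed for the small RNA, WT and Dicer KO samples only, and the counting tool is not stated, although the summary lines of the mRNA table are those that htseq-count writes. Samples were grouped by their labels, and all columns were mapped to a group (0 unmapped); the male control columns of the small RNA table have names that match no sample title, so they were mapped to the group only and are called replicates by the number in the column name.

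The mRNA libraries held 1666836 to 15951775 counts on genes, while 54.8% to 67.7% of each library's total lay on no gene: 40.7% to 54.0% on reads that were not unique and 5.65% to 19.6% outside any feature. At 3 counts, taken as the floor of detection, the level was 0.502 to 1.80 CPM. The small RNA libraries held 2145991 to 2980225 counts. The spread between replicates was above counting error throughout (lowest chi-square per degree of freedom 7.88). Of 47643 gene identifiers 47224 had a symbol in the supplied name table.

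The columns of the mRNA table were checked against the gene identifiers by the Pearson correlation of log2 CPM (0.5 added) with the male WT mean. A group was held to have slipped where r of its mean over the later part of the table was under 0.8: it was 0.355 in male and in female P301S and 0.942 or more in the other groups. For the mean of the slipped columns, the place of the slip was the first window of 25 genes with r under 0.9. This limit was not applied to the other groups, whose windows before that place reached 0.710 in young females and 0.778 in female P301S Dicer KO. The 7 P301S columns left register after gene 7175, with a best shift of up to −16 places where r at that shift was over 0.9, and up to −96 places at a low r near the end of the table. They were not shifted back, since no outside key for the shift was at hand. This changed the plan made before the data were examined: 7 comparisons without P301S libraries were fitted in 28 libraries over all genes, and 8 comparisons with them in 35 libraries over the genes up to that place, with CPM of the counts on that part. The 5 small RNA comparisons were fitted in all 18 libraries, which makes 20 comparisons.

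Genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 15289 genes in the 28 libraries, 5616 in the 35 and 559 of 787 microRNAs. Libraries were scaled by TMM, and contrasts between group means were tested by the quasi-likelihood test of edgeR 4.0.16 (not robust) in R 4.3.3, with Benjamini and Hochberg adjustment over the genes of each contrast and a threshold of 0.05. The SE given with a log2 change is the change over the root of the F statistic; ± after a mean is the SD between libraries. The 15 gene lists, 13 marker lists and 10 microRNA lists were written before the data were examined. Lists with at least 4 tested members were tested by camera of limma 3.58.1 (log2 CPM with a prior count of 2) at a preset correlation of 0.01, again with the correlation estimated from the data, and by fry; p-values were adjusted over the lists of a contrast. List results were also given as members past the threshold, adjusted over all genes and over the list alone. The share of counts on each marker list was compared by a two-sided exact permutation test over all regroupings of the libraries, adjusted over the lists of the comparison. 1 listed gene, Lilrb4a, has no value in the table.

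Genes are named by a rule fixed before the data were examined: with a mean level above the median, the 6 largest rises and 6 largest falls past the threshold, up to 4 members of each list with the smallest adjusted p, the 5 smallest p where fewer than 5 genes passed, and Dicer1, Xist, 4 Y-linked genes, Apoe, Trem2, Clec7a, Cst7, P2ry12 and Tmem119 always. For microRNAs it was the 8 largest rises and 8 largest falls and 7 that were always named. Genes with provisional names were counted but not named. The choroid plexus microRNA list and its score were added after the small RNA results had been seen. Gene coordinates were taken in GRCm38.p6: Dicer1 lies at 12:104687740-104751968 and Apoe at 7:19696244-19701310.

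Alternatives written before the data were examined were RLE scaling, library totals, no filter, a filter of 30 counts, DESeq2 1.42.0, only the compared groups in the model, a block for replicate number, and leaving out each library in turn; a robust fit and the table as deposited were added after. No block was fitted in the 3 comparisons with male small RNA controls, since the numbers of those columns are not tied to sample titles. Whether equal replicate numbers mark pairs was tested by the correlation of residuals between libraries of the same number, which had to be over 0.1 in each of 3 or more pairs; only the P301S male and female small RNA libraries passed (5 pairs, r of 0.142 to 0.534), and blocking them left the count at 0. In data with known changes planted, a 4-fold change was recovered in 69 of 100 genes in Dicer KO against WT males, 39 of 100 in females, 71 of 100 between ages in males, 62 of 100 in P301S Dicer KO against P301S males and 70 of 100 in P301S against WT females; for microRNAs it was 27 of 30 in males and 24 of 30 in females. A 2-fold change was recovered in 17, 6, 8, 18 and 24 of 100 and in 7 and 2 of 30. Changes were planted only in genes with mean counts well above the filter's minimum. All groups were otherwise drawn from a common mean per gene, so these rates can overstate recovery over all tested genes. Seed matches of microRNAs in 3′ ends were not analysed here, since they need a genome sequence. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.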

Results

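Microglia, the resident macrophages of the brain, were profiled in mice that carry the P301S form of human tau (the PS19 line), in mice labelled as lacking Dicer, the enzyme that cuts microRNA precursors into mature microRNAs, and in mice with both changes. Small RNA was sequenced in 18 libraries of freshly isolated microglia at 6 months: 4 from male and 4 from female controls, and 5 from male and 5 from female P301S mice. Messenger RNA was sequenced from its 3′ ends in 35 libraries. At 9 months these were 5 male and 3 female wild types (WT), 4 male and 2 female Dicer knockouts (KO), 3 male and 4 female P301S mice, and 4 male and 4 female P301S Dicer KO mice; at 3 months they were 4 male and 2 female P301S Dicer KO mice, called young here. The small RNA libraries held 2145991 to 2980225 counts on 787 microRNAs. The mRNA libraries held 1666836 to 15951775 counts on genes, and every library but the deepest, a male P301S library, held at most 6792633. The labels do not say whether each library came from a separate animal, so every p-value here measures the spread between these samples only.

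In the mRNA table the values of all 7 P301S libraries stop matching the gene identifiers part of the way down. Up to gene 7175 of 47643 the mean of these columns followed the male WT mean, with a lowest Pearson r of 0.954 across genes in any window of 25 genes. After it the median r was 0.0137. At the best shift against the identifiers the median was 0.967 over genes 8001 to 30000, but r was only 0.166 to 0.397 over genes 40001 to 47000, so no single shift restores the table to its end. The other 28 columns showed no such loss: r after gene 7175 was 0.890 or more in each, in the lowest library against 0.865 before it, and at most 0.361 in the 7 P301S columns. Comparisons without P301S libraries therefore cover 15289 tested genes, and comparisons with them cover the 5616 tested genes before the slip, as CPM, counts scaled to a common total, of the counts on that part of the table. Cx3cr1, P2ry12 and Tmem119, genes that mark resting microglia, lie after it and have no value for P301S mice here. The shift was not undone.

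**Figure D1:**
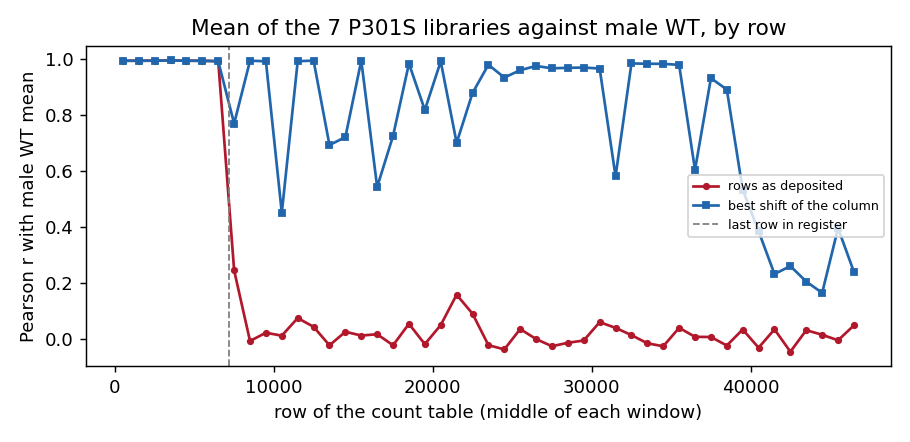
Pearson r, across the genes of each window, between the P301S library mean and the male WT mean (y axis) along the mRNA table (x axis, position in the table), as deposited and at the best shift. The dashed line marks gene 7175; to its right the deposited order has a median r of 0.0137.

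The libraries also fell apart in a way that no label names. Across the genes before the slip, which are not independent replicates, the group means correlated with the male WT mean at r of 0.989 for male P301S and 0.980 for male Dicer KO, but 0.937 for male P301S Dicer KO and 0.948 for the young males. In the 28 libraries in register, whose depth was not matched, 15626 ± 579 genes were detected in male WT (SD, n = 5) and 12684.5 ± 838 in male P301S Dicer KO (n = 4). The labels give no library batch, and the submitters' processing notes name an aligner for WT and Dicer KO but not for P301S, P301S Dicer KO or young mice, a different division. Whether P301S Dicer KO and young libraries were made apart or share an effect of both genotypes is not known here. The strain label is also the same for P301S, P301S Dicer KO and young mice, so these groups rest on the sample titles, and no label says which mice received an inducer of the Cre recombinase.

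What does losing Dicer do to microglia of males without tau pathology? Per the strain labels the Cre recombinase sits in Cx3cr1 in the KO, so KO and WT mice also differ in that allele. Changes between Dicer KO and WT, in males and in females, are therefore not separated from an effect of that allele. Among the genes higher in Dicer KO than in WT males were 11 of 27 disease-associated microglia genes and 5 of 10 border macrophage markers. Apoe, the main lipid carrier of the brain, rose from 1603 ± 329 CPM (SD, n = 5) to 36115 ± 10329 (n = 4), a log2 change of 4.49 ± 0.45 (SE; adjusted p = 1.34e-08). The receptor tyrosine kinase Axl rose by 4.50 ± 0.49 on the log2 scale (7.33e-08), Gpnmb, a glycoprotein of lipid-laden macrophages, by 6.03 ± 0.84 (7.4e-06), and Clec7a, the β-glucan receptor, by 3.39 ± 0.52 (5.1e-05). Gpnmb was at 54.0 ± 73.1 CPM (9.91 to 163) in Dicer KO and 0.792 (0.189 to 1.56) in WT males; without Dicer KO replicate 1 its change was 4.40 and that of Clec7a 2.72, both past the threshold. Of the disease-associated genes 3 fell, and adjusted over the list alone 16 rose and 4 fell; the list's adjusted p was 4.07e-11, but 0.155 with an estimated correlation. Trem2, a receptor on which that state depends, was at 1203 ± 345 against 1007 ± 94.4 CPM and did not pass (0.823).

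Among 10 border macrophage markers 5 rose, including Ms4a7 from 12.5 ± 4.04 to 363 ± 91.2 CPM (log2 change 4.86 ± 0.39, adjusted p = 8.02e-11) and the mannose receptor Mrc1 (2.36 ± 0.35), and the list held with an estimated correlation (adjusted p = 0.00737); adjusted over the list alone 6 rose. These markers took 0.234% ± 0.0319 of the counts in Dicer KO males against 0.0664% ± 0.0143 in WT males (two-sided exact permutation p = 0.00794; 0.0762 after adjustment over 16 lists). Interferon response genes rose in 7 of 30 cases, Ifi204 by 1.71 ± 0.36 among them (11 adjusted over the list alone; adjusted p = 0.036 with an estimated correlation). Antigen presentation genes rose in 6 of 20 (7 over the list alone), with H2-Eb1, a class II molecule, at 1.61 ± 0.34 (list adjusted p = 0.0699 with an estimated correlation). The cytokine gene Il1b rose by 2.17 ± 0.37, 1 of 3 that rose among 26 cytokine and NF-κB genes.

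Resting-state genes went the other way. Of 20 homeostatic microglia genes 6 fell and none rose (11 fell adjusted over the list alone; list adjusted p = 0.0398 with an estimated correlation). Sall1, a transcription factor of microglial identity, fell by 1.55 ± 0.25 on the log2 scale (adjusted p = 9.85e-05), Rhob fell by 1.59 ± 0.25 and the protease inhibitor Cst3 fell by 1.27 ± 0.27. Cx3cr1, the fractalkine receptor, fell from 10381 ± 1422 to 4196 ± 764 CPM, but per the strain labels the Cre recombinase sits in this gene in the KO, so its level compares mice with different alleles of it. P2ry12 (−0.85 ± 0.28, 0.106) and Tmem119 (−0.60 ± 0.22, 0.196) did not pass. Immediate early genes fell in 10 of 23 cases (17 over the list alone), Egr1 from 4791 ± 2319.8 to 1001 ± 257 CPM among them, and the list's adjusted p was 0.0677 with an estimated correlation. Of 12 endothelial markers only the glucose transporter gene Slc2a1 passed, and it fell by 1.47 ± 0.40, a call lost with some library left out (7 fell adjusted over the list alone; list adjusted p = 0.114 with an estimated correlation); these markers held 0.0621% ± 0.0232 of counts against 0.134% ± 0.0262 (exact permutation p = 0.0159, 0.0762 adjusted).

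Dicer1 itself was at 33.0 ± 9.32 CPM in Dicer KO and 30.6 ± 7.19 in WT males (log2 change 0.11 ± 0.32). Reads from the 3′ end lie outside a deletion further upstream, so this level checks neither the deletion nor the labels. In all, 257 genes were higher and 103 lower by edgeR's quasi-likelihood test at an adjusted p under 0.05. Without Dicer KO replicate 1 the total of 360 went to 226. With only the compared groups in the model it was 1427 and with replicate numbers as a block 582; DESeq2 gave 615 and leaving out the filter on low counts 591.

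**Figure D2:**
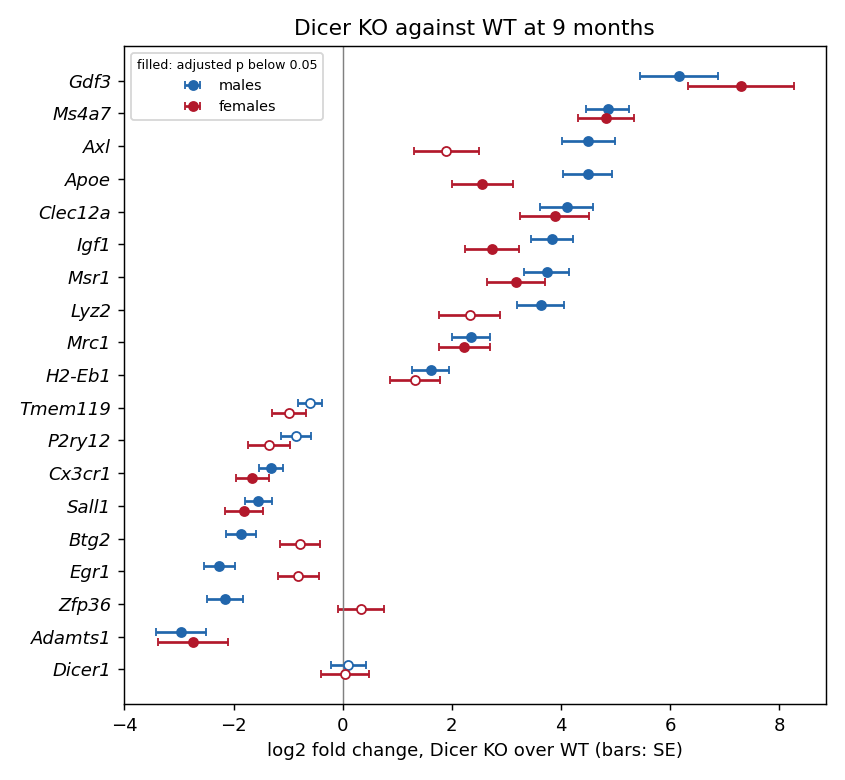
Log2 change of 19 genes in Dicer KO against WT microglia at 9 months, with bars of 1 standard error; males (4 against 5 libraries) and females (2 against 3) are separate points, filled where the adjusted p was under 0.05. Apoe changed by 4.49 in males and 2.56 in females. Cx3cr1 fell in both, but its allele differs between Dicer KO and WT mice.

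In females, with 2 Dicer KO and 3 WT libraries, fewer genes passed. Ms4a7 rose from 11.5 ± 1.99 to 328 ± 147 CPM (log2 change 4.83 ± 0.52, adjusted p = 2.22e-07), the scavenger receptor Msr1 by 3.18 ± 0.53 and the growth factor Igf1 by 2.74 ± 0.49. Apoe rose by 2.56 ± 0.55 (0.0222), with a WT mean of 4129 ± 4385 CPM that replicate 1 at 9135 pulls up (change of 3.91 without it, and 1.69 without Dicer KO replicate 1). Border macrophage markers rose in 3 of 10 cases (4 over the list alone; list adjusted p = 0.00355 with an estimated correlation). All 20 homeostatic genes were lower and 3 fell, Sall1 by 1.80 ± 0.35, Crybb1 by 1.93 ± 0.44 and Cx3cr1 by 1.65 ± 0.31, with 13 passing over the list alone (list adjusted p = 0.0015 with an estimated correlation). The level of Cx3cr1 again compares mice with different alleles of it. Clec7a (1.00 ± 0.66) and Cst7, a cathepsin inhibitor (0.08 ± 0.84), did not pass, and 2 of 27 disease-associated genes rose (4 rose and 1 fell over the list alone; adjusted p = 0.704 with an estimated correlation). In WT females Clec7a spread from 38.0 to 453 CPM (mean 179 ± 238) and Cst7 from 11.7 to 231 (85.4 ± 126). Each of these WT means is pulled up by its highest library. In Dicer KO females Clec7a was at 192 to 521 CPM and Cst7 at 60.1 to 121. Dicer1 was at 38.4 ± 2.78 against 37.2 ± 14.1 CPM. In all 35 genes rose and 5 fell. Without female Dicer KO replicate 1 the total of 40 went to 19, without WT replicate 2 to 24 and without WT replicate 3 to 26. Apoe, Mrc1, Cx3cr1, Igf1, Sall1 and Crybb1 each lost their call with some library left out; Ms4a7 and Msr1 did not. The rise of Igf1 was 3.56 without WT replicate 1 and the change of Sall1 −2.41 without Dicer KO replicate 2. Without either Dicer KO library that group has 1 library, and the spread then comes from the other groups. DESeq2 gave 92, leaving out the filter 116, the compared groups alone 80 and the block 314.

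Did the effect of Dicer loss differ between the sexes? No gene passed the test of the difference (edgeR; 270 of 15289 genes at an unadjusted p under 0.05, and 2 genes by DESeq2; 24 without the filter). The gene with the smallest p, Zfp36, which encodes an RNA-destabilising protein, had a male minus female difference of −2.48 ± 0.53 (adjusted p = 0.53), and the differences for Cst7 (4.24 ± 1.14) and Apoe (1.93 ± 0.70) did not pass. In males alone Cst7 rose by 4.32 ± 0.68 (adjusted p = 7.16e-05). Dicer KO replicate 1 raised that change, at 891 CPM against 54.9 to 73.7 in the other Dicer KO males. The difference for Cst7 also rests on the WT females, which spread from 11.7 to 231 CPM. Immediate early genes stood out as a list (median change lower in males, adjusted p = 1.58e-12), but not with an estimated correlation (adjusted p = 0.334).

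Microglia of P301S Dicer KO males aged from 3 to 9 months gained the disease-associated genes broadly. Of 27 such genes 22 rose and 1 fell (24 and 1 adjusted over the list alone; adjusted p = 0.0371 with an estimated correlation). Apoe rose from 921 ± 246 to 23088 ± 11624 CPM (n = 4 each; log2 change 4.65 ± 0.50, adjusted p = 5.13e-08), Clec7a by 3.86 ± 0.59, Cst7 by 4.20 ± 0.74 and the tetraspanin gene Cd63 by 3.34 ± 0.36. Cytokine and NF-κB genes rose in 10 of 26 cases, Cxcl2, a neutrophil attractant, by 3.34 ± 0.45 and the NF-κB inhibitor Tnfaip3 by 3.75 ± 0.55 (13 over the list alone; adjusted p = 0.0371 with an estimated correlation). Interferon genes rose in 12 of 30, Ifi204 by 2.97 ± 0.41 and Bst2, an antiviral tether, by 2.29 ± 0.48 (17 over the list alone; 0.0266). Without 9-month replicate 2 the rise of Cxcl2 was 2.69.

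In the same males P2ry12, a purinergic receptor of resting microglia, fell from 2238 ± 182 to 592 ± 252 CPM (log2 change −1.92 ± 0.30, adjusted p = 4.3e-05). It was 1 of 11 homeostatic genes of 20 that fell, with P2ry13 (−1.22 ± 0.23); 2 rose, among them the Fc receptor-like gene Fcrls (2.07 ± 0.31), and the list's call was lost with an estimated correlation (adjusted p = 0.158). Lysosome genes rose in 10 of 33 cases, Lamp1 by 1.21 ± 0.22 (14 rose and 1 fell over the list alone; 0.0857), and immediate early genes in 8 of 23 (0.298). Ribosomal protein genes rose in 16 of 62 (29 over the list alone; 0.0596), though reads shared with pseudogenes leave their levels uncertain. Antigen presentation genes rose in 5 of 20 (0.298), lipid handling genes in 4 of 22, Plin2 of lipid droplets by 2.37 ± 0.45, and oxidative phosphorylation genes rose in 5 and fell in 1 of 43 (0.515). Of 13 microRNA pathway genes only Tnrc6a passed, and it fell by 0.90 ± 0.26, a call lost with some library left out. Trem2 (0.62 ± 0.24, 0.0875) and Tmem119 (−0.35 ± 0.23) did not pass, and Dicer1 was at 44.7 ± 21.7 against 44.1 ± 8.49 CPM.

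Markers of other brain cells fell over the same interval. Neuronal markers fell in 6 of 14 cases, the noncoding RNA Meg3 by 1.72 ± 0.34 (10 over the list alone; adjusted p = 0.00493 with an estimated correlation), and their share of counts went from 0.0710% ± 0.00643 at 3 months to 0.0162% ± 0.00219 at 9 months (exact permutation p = 0.0286, the smallest that 4 against 4 allows; 0.0653 adjusted). The astrocyte transporter gene Slc1a2 fell by 1.85 ± 0.30 and was 1 of 4 of 13 astrocyte markers that fell, while 1 rose (0.103 with an estimated correlation; share 0.0439% ± 0.00799 against 0.137% ± 0.0457). Mural markers fell in 3 of 8, Acta2 of smooth muscle by 1.93 ± 0.49 (0.1; share 0.00997% ± 0.00302 against 0.0470% ± 0.0157). Border macrophage markers rose in 4 of 10, Ms4a7 by 4.27 ± 0.43 (4.97 without young replicate 4; 0.0596; share 0.115% ± 0.0478 against 0.0522% ± 0.00911). In all 655 genes rose and 644 fell by edgeR; DESeq2 called 1999, the compared groups alone 513 and the block 372.

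In females the comparison had only 2 young libraries. Apoe rose from 909 ± 54.7 to 15819 ± 5503 CPM (log2 change 4.12 ± 0.65, adjusted p = 0.000272), Fcrls by 3.13 ± 0.44, Cd63 by 2.65 ± 0.46 and Runx3, a transcription factor of blood lineages, by 7.63 ± 0.93 (6.60 and 11.42 without young replicates 1 and 2). P2ry12 fell by 1.85 ± 0.34 (0.00142) and Slc1a2 by 1.49 ± 0.34. Clec7a (1.63 ± 0.70, 0.174) and Cst7 (2.40 ± 0.92, 0.132) did not pass. Disease-associated genes rose in 3 of 27 cases (12 over the list alone; adjusted p = 0.563 with an estimated correlation), immediate early genes in 4 of 23 (11 over the list alone; 0.563), border macrophage markers in 4 of 10 (5 over the list alone; 0.542) and interferon genes in 2 of 30 (5 over the list alone; 0.542). In all 271 genes rose and 213 fell. The total of 484 rests on few libraries: it was 78 without young replicate 1, 826 without young replicate 2, 868 without 9-month replicate 3, 318 without 9-month replicate 1 and 320 without 9-month replicate 4. DESeq2 gave 1234, leaving out the filter 796 and the compared groups alone 103. Without either young library that group has 1 library, and the spread then comes from the other groups. Apoe, Fcrls, Cd63, Runx3 and P2ry12 kept their calls with any of the 4 9-month libraries left out. Whether the age effect differed between the sexes was not tested.

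**Figure D3:**
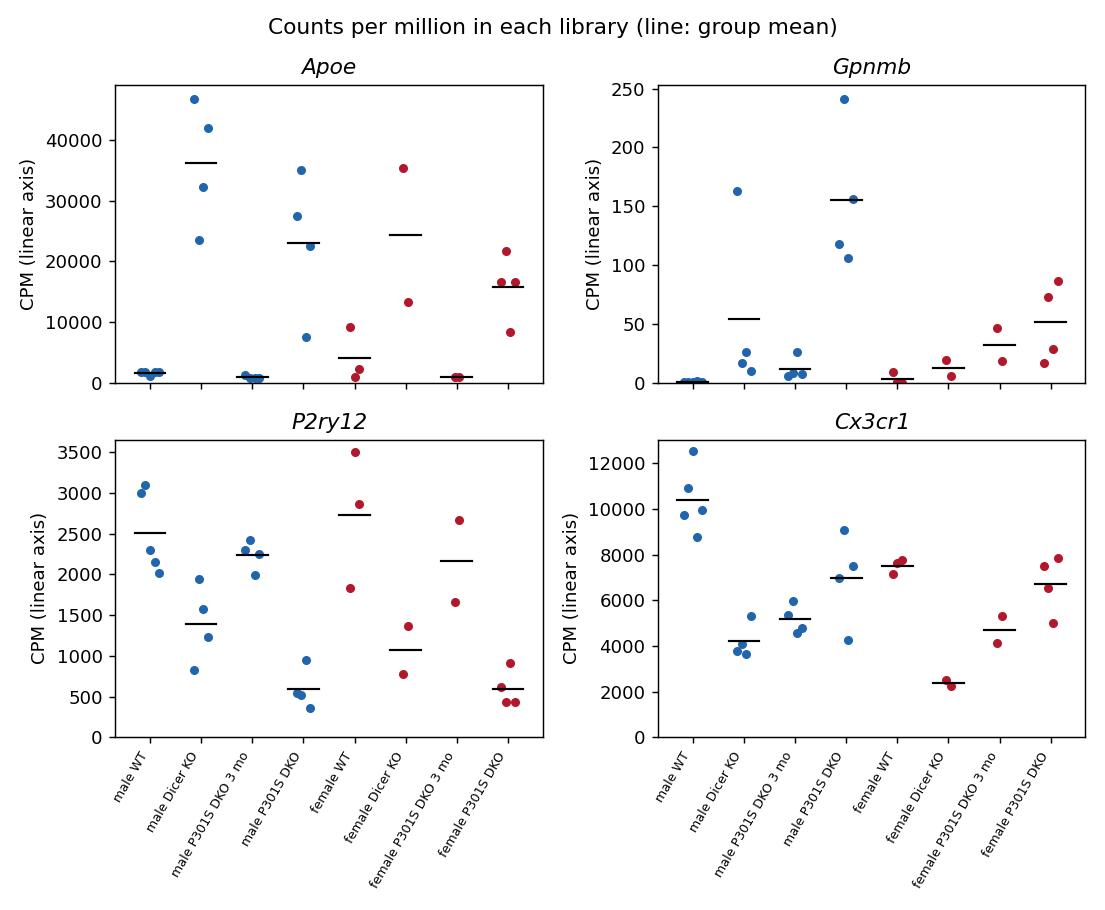
Level in CPM (linear axis) of Apoe, Gpnmb, P2ry12 and Cx3cr1 in each of the 28 libraries in register, by group; points are libraries and lines are group means, with 3 mo marking the young mice and P301S DKO the P301S Dicer KO mice. Mean Apoe was 1603 CPM in WT males, 36115 in Dicer KO males, 921 in young and 23088 in 9-month P301S Dicer KO males.

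What does losing Dicer add in P301S mice? The contrast measures this only if the titles mark Dicer loss, since the strain labels of both groups are equal. Over the 5616 genes that could be compared, 490 genes were higher and 539 lower in P301S Dicer KO than in P301S males, and 732 and 689 in females. Border macrophage markers rose in 4 of 4 measured cases in each sex, Ms4a7 by 4.01 ± 0.47 in males (adjusted p = 6.37e-08) and 3.38 ± 0.40 in females and Mrc1 by 2.44 ± 0.43 (1.71 without male P301S Dicer KO replicate 2) and 1.93 ± 0.38 (list adjusted p = 0.0247 in males and 0.0671 in females, with an estimated correlation); in females they held 0.113% ± 0.0241 of counts against 0.0252% ± 0.00788 (exact permutation p = 0.0286, 0.0952 adjusted). The other markers were Cd163 (2.22 ± 0.50 in males, 2.55 ± 0.46 in females) and Cbr2 (1.88 ± 0.48 and 1.88 ± 0.44). Neither passed between Dicer KO and WT mice, where Cd163 changed by 0.06 in males and −0.02 in females and Cbr2 by 0.37 and 1.00. Apoe rose in females, from 8718 ± 3198 to 38127 ± 13031 CPM (log2 change 2.13 ± 0.52, adjusted p = 0.00192), while in males its change of 1.00 ± 0.55 did not pass. Psap, which encodes a lysosomal lipid-binding precursor, fell by 3.26 ± 0.33 in males and 3.22 ± 0.32 in females, Cst3 by 1.79 ± 0.31 and 1.52 ± 0.29. Disease-associated genes went both ways, with 2 up and 3 down of 17 in males and 3 up and 9 down in females. Cytokine and NF-κB genes fell in 3 of 15 cases in males, the cytokine gene Tnf by 1.70 ± 0.40, and in 6 of 15 in females, Nfkb1 by 1.81 ± 0.26 (7 over the list alone). Lysosome genes rose in 2 and fell in 7 of 18 in males and rose in 2 and fell in 8 in females.

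Some of the smallest p-values belonged to ribosomal protein genes. Rps25 was at 2260.4 ± 600.1 against 84.0 ± 27.1 CPM in males, with 11 of 19 such genes up and 1 down (adjusted p = 0.123 with an estimated correlation), and 11 up and 2 down in females (0.281). The same gene changed by 4.29 between young P301S Dicer KO and Dicer KO males, and across these 19 genes, not independent replicates, those changes correlated at r = 0.972 with the changes between P301S Dicer KO and P301S males. Across all 5616 tested genes that r was 0.230. Ribosomal protein genes held 3.54% ± 0.484 of counts against 1.85% ± 0.269 in males (exact permutation p = 0.0286, 0.143 adjusted), and neuronal markers 0.0541% ± 0.0131 against 0.0115% ± 0.00553 in females (0.0286, 0.0952 adjusted). All 6 measured neuronal markers were higher in females and 2 passed, Meg3 (381 against 18.5 CPM) and Nefl (32.0 against 3.13). The difference in share therefore rests largely on the noncoding RNA Meg3. Without P301S replicate 1 the male total of 1029 went to 684 and without replicate 2 to 670; the compared groups alone gave 244 and the block 224. The effect differed between the sexes for 2 genes, Aar2 of the splicing machinery (−3.58 ± 0.72, adjusted p = 0.0384, and −2.93 without female P301S Dicer KO replicate 3) and the collagen gene Col18a1, at 0 CPM in the male P301S Dicer KO libraries. Aar2 lost its call without any 1 of 9 libraries and Col18a1 without male P301S replicate 1 or female P301S replicate 4. No gene was called for this difference with only the compared groups in the model or with the block, while DESeq2 called more.

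Was the effect of Dicer loss different with and without P301S? In males 235 genes had a higher and 186 a lower change with P301S. Apoe (difference −3.45 ± 0.72, adjusted p = 0.00159) and Axl (−3.84 ± 0.78, 0.00128) changed less with P301S, where 2 of 3 libraries without Dicer loss already lay above every WT library. Apoe was at 27205 ± 24680.1 CPM in P301S and 3668 ± 753 in WT males on this scale, and at 54361 ± 27251 in P301S Dicer KO and 79860.1 ± 22288 in Dicer KO males. The lowest P301S library, at 3838 CPM of Apoe and 122 of Axl, lay within the WT range (2350 to 4183 and 78.3 to 124). Without P301S replicate 2 the Apoe difference was −2.52 (0.0302). Disease-associated genes had a lower change in 5 of 17 cases (8 over the list alone), interferon genes in 3 of 8 (adjusted p = 0.408 with an estimated correlation) and lysosome genes in 4 of 18, with 1 higher. Immediate early genes had a higher change in 5 of 12, Rgs1, a regulator of chemokine signalling, by 2.19 ± 0.43 (0.408). In females, where Apoe did not pass (−0.45 ± 0.81), 167 genes had a higher and 114 a lower change, Hmox1, the haem-degrading enzyme, by 4.58 ± 0.67 (3.76 without WT replicate 1, 5.30 without Dicer KO replicate 1) and Psap by −3.16 ± 0.48. If the P301S Dicer KO libraries were made apart from the other 9-month ones, that difference stays in this contrast. Without male P301S replicate 2 the male total of 421 went to 236, and the block also lowered it by more than 1.5 times. The female total of 281 went to 93 without Dicer KO replicate 2, also fell by more than 1.5 times without Dicer KO replicate 1, each of which leaves 1 library in that group, and DESeq2 gave 422.

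Few genes separated the mice titled P301S from WT. In males 13 genes rose and 1 fell. Apoe rose by 2.89 ± 0.51 (adjusted p = 0.00302), the lipase gene Lpl from 60.6 ± 23.7 to 884 ± 754 CPM (3.87 ± 0.76, 0.011), Axl by 3.25 ± 0.56 and Il1b by 2.64 ± 0.46; Hnrnph1, an RNA-binding protein gene, fell by 1.58 ± 0.33. For Apoe, Lpl, Axl and Il1b 2 of the 3 P301S libraries lay above every WT library, and without replicate 2 Apoe rose by 1.96, Lpl by 3.20 and Il1b by 1.97, none past the threshold. Disease-associated genes rose in 4 of 17 cases (10 over the list alone; adjusted p = 0.0709 with an estimated correlation) and interferon genes in 2 of 8 (5 over the list alone; 0.00427). Neutrophil markers held 0.0710% ± 0.0408 of counts against 0.0281% ± 0.0136 in WT males, and monocyte markers 0.0380% ± 0.0140 against 0.0202% ± 0.00527 (exact permutation p = 0.0536 each, 0.179 adjusted; on mean log2 CPM 0.0357 each, 0.134 adjusted). Trem2 did not pass (0.33 ± 0.22). The count of 14 was 0 without P301S replicate 2 (unadjusted p-values were not tallied for that fit), 3 without replicate 3, 50 without replicate 1, and 7, 9, 8 and 8 without WT replicates 2, 3, 4 and 5. The compared groups alone gave 5 and the block 0. In females no gene passed (edgeR; 70 of 5616 at an unadjusted p under 0.05, 0 by DESeq2, 2 with the block): Apoe was at 8718 ± 3198 against 9305 ± 9654 CPM and the smallest p belonged to Sdc3, a heparan sulfate proteoglycan gene (1.53 ± 0.45). Interferon and ribosomal protein genes were higher as lists with an estimated correlation (adjusted p = 0.0429 and 0.0432), but neither passed by fry (adjusted p = 0.227 each). Between P301S males and females no gene passed either (edgeR; 250 at an unadjusted p under 0.05, 0 by DESeq2); S100a6, a calcium-binding protein gene, differed by 1.86 ± 0.42 (0.427) and Apoe by 1.64 ± 0.54 (0.848). Neutrophil markers held 0.0710% ± 0.0408 of counts in these males and 0.0170% ± 0.00343 in females, and monocyte markers 0.0380% ± 0.0140 and 0.0180% ± 0.00126 (exact permutation p = 0.0286 each, 0.143 adjusted; lists 0.0644 and 0.0799 with an estimated correlation).

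WT males and females differed in few genes beyond the sex-linked ones. Xist, the noncoding RNA that silences an X chromosome, was at 841 ± 275 CPM in females and 2.90 ± 0.791 in males, and all 4 Y-linked genes were higher in males, Ddx3y by 6.96 ± 0.40 (adjusted p = 1.59e-15; 7.63 without female replicate 2). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were lower in males by edgeR, by −2.66 ± 0.37 (−1.95 without female replicate 2) and −2.23 ± 0.33, and took 0.968% ± 0.377 of counts in males against 4.80% ± 3.11 in females; such transcripts reach a poly(A)-selected library unevenly. Of 14 neuronal markers Syt1 fell, a call lost with some library left out, with 1 of 5 male libraries below every female one, and the list passed with an estimated correlation (adjusted p = 0.0413). Apoe (−1.36 ± 0.43, 0.605) and Clec7a (−2.26 ± 0.53, 0.108) did not pass. In all 4 genes were higher and 9 lower in males; the total of 13 was 32 without female WT replicate 1, 27 by DESeq2, 56 without the filter, 5 in the compared groups alone and 6 with the block.

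Between P301S Dicer KO males and females at 9 months 16 genes were higher and 18 lower in males. Besides Xist and the 4 Y-linked genes, the chemokine gene Ccl6 was higher in males (779 ± 528 against 151 ± 35.3 CPM, log2 difference 2.37 ± 0.48, adjusted p = 0.0207, a call lost with some library left out), as was the calcium-binding protein gene Rcn2 (2.20 ± 0.46); Aar2 was lower (−3.19 ± 0.60; −2.53 without female replicate 3). Of 27 disease-associated genes 26 were higher in males, with 1 passing over all genes and 19 over the list alone (adjusted p = 0.219 with an estimated correlation). Neuronal markers held 0.0162% ± 0.00219 of counts in males and 0.0426% ± 0.0097 in females (exact permutation p = 0.0286, 0.229 adjusted), and 7 of 14 fell over the list alone (0.00758 with an estimated correlation). The total of 34 was 160 without male replicate 1, 127 without male replicate 2 or female replicate 3, 57 and 61 without male replicates 3 and 4, and 63 without female replicate 2 or 4. DESeq2 gave 640, leaving out the filter 292, the compared groups alone 13 and the block 18.

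Which microRNAs follow tau pathology, and does sex matter? In males at 6 months 15 microRNAs were higher and 43 lower in P301S than in control microglia. Among those higher in P301S were 3 members of the miR-29 family, which limits matrix genes: miR-29a-3p was at 67292 ± 18007 CPM (n = 5) against 27479 ± 12187 (n = 4), a log2 change of 1.29 ± 0.33 (adjusted p = 0.0234), miR-29b-3p rose by 1.19 ± 0.30 and miR-29c-3p by 1.65 ± 0.39. The myeloid miR-142a-5p rose by 1.31 ± 0.30 (0.0171). The largest falls included miR-30c-5p, from 19777 ± 11588 to 2505 ± 1748 CPM (−2.98 ± 0.72, 0.0171), miR-20b-5p (−3.12 ± 0.57) and miR-764-5p, a microRNA of an intron of Htr2c (−2.38 ± 0.45). miR-764-5p is on a list of choroid plexus microRNAs drawn up after the results were seen, whose mean log2 CPM was 7.41 ± 0.38 in these controls and 5.93 ± 0.57 in P301S males. Of the inflammation-linked microRNAs, miR-146a-5p (0.47 ± 0.22, 0.171), miR-21a-5p (0.55 ± 0.19, 0.0738), miR-155-5p (−0.06 ± 0.41) and miR-223-3p (−0.12 ± 0.25) did not pass; 1 of 37 on that list rose and 3 fell. Members of the miR-29 and miR-30 families rose in 3 of 18 cases and fell in 1, X-linked ones rose in 1 and fell in 10 of 48, let-7 ones rose in 2 and fell in 1 of 20, and miR-17-92 ones fell in 2 of 19; none of these lists passed. The X-linked list shares miR-448, miR-1264 and miR-1298 with the choroid plexus list. The calls of miR-20b-5p and miR-764-5p held with any library left out, and those of the miR-29 members, miR-142a-5p and miR-30c-5p did not. With library totals in place of scaling factors 7 were higher and 39 lower. The total of 58 was 6 without male control replicate 2, 12 and 14 without P301S replicates 1 and 2, 31 without control replicate 1, 35 without P301S replicate 4, 97 without P301S replicate 5 and above that without control replicate 3. DESeq2 gave 99 and the compared groups alone 32.

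In females no microRNA passed (edgeR; 32 of 559 at an unadjusted p under 0.05, 1 by DESeq2). miR-30c-5p was at 6719.8 ± 5208 CPM in P301S and 1103 ± 661 in control females (2.61 ± 0.75, adjusted p = 0.46), and miR-146a-5p changed by −0.04 ± 0.22. The P301S effect differed between the sexes for 27 microRNAs, 3 with a higher and 24 with a lower change in males: miR-142a-5p by 1.69 ± 0.42 (0.0209), miR-30c-5p by −5.59 ± 1.04 (0.00688) and miR-20b-5p by −4.18 ± 0.84. Along the same contrast the choroid plexus score went from 7.41 to 5.93 in males and from 4.98 to 5.53 in females, so a difference in tissue between the libraries is not separated from a sex difference in the response. The X-linked list had a lower change in 6 of 48 cases and the endothelial and mural list in 3 of 7 (adjusted p = 0.976 with an estimated correlation). The overlap of the X-linked list with the choroid plexus list applies here too. miR-142a-5p lost its call with some library left out, while miR-30c-5p and miR-20b-5p did not. The total of 27 was 16 without female control replicate 1 or 2, 14 without female control replicate 4, 44 without male control replicate 4 and 62 without male P301S replicate 5; DESeq2 gave 57.

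Between control males and females 57 microRNAs were higher and 33 lower in males, whereas between P301S males and females none passed (edgeR; 12 at an unadjusted p under 0.05, 0 by DESeq2; smallest p for miR-210-3p, −0.81 ± 0.27). miR-30c-5p was higher in control males by 4.16 ± 0.82 (adjusted p = 0.00205), miR-20b-5p by 3.59 ± 0.65 and miR-204-5p, abundant in choroid plexus, by 3.32 ± 0.50, at 24478 against 2454 CPM. miR-142a-5p (−1.57 ± 0.32, 0.00228) and miR-146a-5p (−0.82 ± 0.23, 0.0201) were lower in control males, the latter a call lost with some library left out. Of 18 measured microRNAs known from choroid plexus or ciliated epithelium, on the list drawn up after this comparison had been seen, 16 were higher in control males; their mean log2 CPM was 7.05 to 7.86 in the 4 male controls and 4.02 to 5.77 in the 4 female controls. The endothelial and mural list rose in 3 of 7 cases (0.969 with an estimated correlation), and X-linked ones rose in 9 and fell in 6 of 48. These X-linked rises include both arms of miR-448, miR-1264 and miR-1298, which are also on the choroid plexus list. The total of 90 was 54 without male control replicate 2 and 55 without female control replicate 2, and 58 with the compared groups alone.

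**Figure D4:**
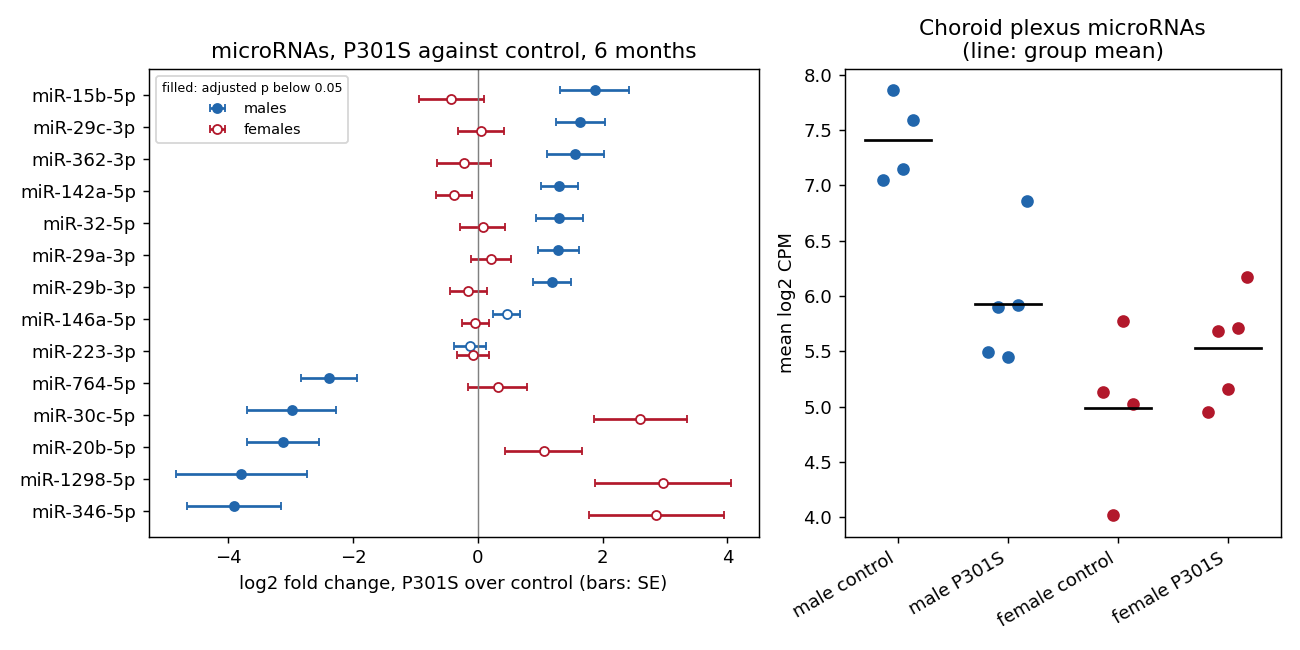
Left, log2 change of 14 microRNAs in P301S against control microglia at 6 months by sex, with bars of 1 standard error, filled where the adjusted p was under 0.05; right, mean log2 CPM of choroid plexus microRNAs in each library of the 4 groups. The 4 male control libraries, at 7.05 to 7.86, lie above the other 14, which reach at most 6.86.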

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

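The sequencing depth test and the splits of Dicer KO against WT males and of WT males against females had their reading written before those tests ran; the other tests in this part were chosen after the result was seen. Of those, the counts with a library left out, with library totals and of the interaction come from fits planned before the data were examined, and only their use as tests of an explanation was chosen after. The measure of the set difference was changed after its first outcomes were seen: across the 19 ribosomal protein genes r was 0.972 in males and 0.921 in females, across called genes 0.497 and 0.506, and the last measure is the share with equal sign. By the bound first written, an r of 0.5, the males would have counted against a set difference. Across all genes that r was only 0.230 in males and 0.248 in females. The measure for Dicer loss alone was also changed, from r across all genes (0.237 in males, 0.176 in females) and across called genes (0.406, 0.252) to a count from the interaction.

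In Dicer KO males activation genes and border macrophage markers were higher together. More border macrophages among the sorted cells would raise all their markers alike only if no other cells supplied these transcripts. Ms4a7 changed by 4.86 and Cd163 by 0.06 (chi-square test of equal changes, p = 3.19e-25). In WT males Ms4a7 was at 12.5, Cd163 at 19.3 and Stab1 at 323 CPM. The part of these levels that comes from microglia is not known, and such a part would make a marker's change smaller. The test therefore cannot decide whether such cells were more frequent. The count of called genes stayed at 226 or more with any library left out. A rise of such cells, in the same or another state, and a change within microglia all stay open.

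Between P301S Dicer KO and P301S males 1029 genes differed. Loss of Dicer alone is argued against as the whole cause by 421 genes whose Dicer effect differed with P301S, and depth by 931 genes left (879 of them shared) after thinning the libraries to 823089 counts; in females 1371 were left at 1172430 counts. A difference between sets of libraries stays open: 82.5% of the called genes in males and 78.2% in females had the same sign between young P301S Dicer KO and Dicer KO mice, but a joint effect of both genotypes predicts the same. Between Dicer KO and WT mice the share of these genes with the same sign was 63.5% in males and 60.2% in females. No label defines such sets of libraries, which were read from the expression values alone. If they exist as read, a constant shift does not cancel in the interaction of Dicer and P301S, as the plan had stated.

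Between male and female controls 90 microRNAs differed. Choroid plexus tissue in the male control libraries is a candidate explanation: the 41 other microRNAs higher in male controls followed the choroid plexus score within the 14 other libraries at a median r of 0.495, against −0.0146 for those not called (100000 permutations, p = 0.00679). Scaling leaves 78 with library totals and leaving out any library at least 54, which argues against both. The 33 microRNAs lower in male controls had a median r of −0.407 with the choroid plexus score in the same 14 libraries, without a permutation test. They could be part of the same difference in tissue. So could the rises and falls in P301S males and the 27 that differ in the P301S effect by sex, which share these controls. Sex and tissue carry-over stay open.

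Regrouping the libraries gave as many genes, the real grouping included, in 1 of 60 groupings for Dicer KO against WT males (highest other 194), 1 of 35 for age in males (40), 1 of 35 for P301S Dicer KO against P301S males (709) and females (7). It did so in 1 of 60 for the interaction of Dicer and P301S in males (380), 1 of 56 for WT males against females (7), 1 of 35 for control males against females (21), 2 of 100 for microRNAs in P301S males (69) and 3 of 100 for their interaction with sex (34). It gave as many in 3 of 56 for P301S against WT males (14), 12 of 35 for P301S Dicer KO males against females (270) and 20 of 60 for the sex interaction of that effect (27), so these counts are not told apart from other groupings. Where the count was 0 all groupings reached it: 100 of 100 for microRNAs in P301S females (highest other 0) and between P301S sexes (12), 35 of 35 for P301S males against females (0) and P301S against WT females (5). Where many groupings were possible a random part was run, as 60 of 126 for Dicer KO against WT males. It was 60 of 3920 for the interaction of Dicer and P301S and 100 of 17640 for that of microRNAs with sex. Interactions were regrouped by exchanging sex or P301S status within pairs of groups. Where the exchanged groups themselves differ, this widens the spread, so a low share does not by itself show an interaction. Comparisons with a group of 2 libraries were not regrouped.

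Effects that differed between groups were 2 genes for sex in the P301S Dicer KO effect, 421 in males and 281 in females for Dicer with P301S, and 27 microRNAs for sex in the P301S effect. Counts not used here because they lie past the slip had a median of 3147249 in the 7 P301S libraries (2266455 to 8234820).

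Dixon's test set 11 of 199 values apart, with 9.95 expected. Apoe was 1019 CPM in male WT replicate 3 (others 1696 to 1799) and 1288 in young male replicate 1 (764 to 817), and Cst7 891 in male Dicer KO replicate 1 (54.9 to 73.7). miR-146a-5p was 23538 CPM in female P301S replicate 5 (44162 to 52159), and in female control replicate 3 miR-155-5p was 119 (34.7 to 38.4) and miR-21a-5p 16094 (10186 to 10698). In female P301S Dicer KO replicate 2 mural markers held 0.0444% (0.0119 to 0.0139) and choroid plexus markers 0.721% (0.0677 to 0.174). T and NK cell markers held 0.000248% in male P301S Dicer KO replicate 3 (2.33e-05 to 4.67e-05), and erythroid markers 0.00929% in male WT replicate 4 (0.000483 to 0.00144) and 0.00114% in male P301S Dicer KO replicate 2 (4.13e-05 to 0.000172). The cause was not tested.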

How the results depend on the processing

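The robust fit and the table as deposited were chosen after the result was seen. The other settings were chosen before the data were examined, and counts are named here where they moved by more than 1.5 times. DESeq2 gave 99 for microRNAs in P301S males (58 in the fit reported), 1 in females (0), 57 for their interaction (27). It gave 615 and 92 for Dicer KO in males and females (360, 40), 2 for that interaction (0), 1999 and 1234 for age (1299, 484). For sex in WT it gave 27 (13), and 640 for sex in P301S Dicer KO (34), with 20 for the sex interaction of the P301S Dicer KO effect (2) and 422 for Dicer with P301S in females (281). Without the filter there were 591 and 116 for Dicer KO, 24 for its interaction, 796 for age in females, 56 and 292 for sex in WT and P301S Dicer KO, and 1 for the sex interaction of the P301S Dicer KO effect. With only the compared groups in the model there were 32 for microRNAs in P301S males, 58 for sex in controls (90), 1427 and 80 for Dicer KO, 513 and 103 for age, 5 and 13 for sex in WT and P301S Dicer KO. There were 244 for P301S Dicer KO against P301S males (1029), 0 for its sex interaction and 5 for P301S against WT males (14). With the replicate number as a block there were 582 and 314 for Dicer KO, 372 for age in males, 6 and 18 for sex, 224 for P301S Dicer KO against P301S males, 0 for its sex interaction, 0 and 2 for P301S against WT in males and females, and 1.5e+02 for Dicer with P301S in males (421). For the P301S male and female small RNA libraries the block left the count at 0. In Dicer KO and WT females both pairs of equal number were over 0.1 (r of 0.153 and 0.240), but 2 pairs are too few for the rule used. No block was fitted in the 3 comparisons with male small RNA controls, because the numbers in those column names are not tied to sample titles. With the slip left in, there were 24 for Dicer KO in females, 7 and 161 for sex in WT and P301S Dicer KO, 24 for sex in P301S, 11819 and 12341 for P301S Dicer KO against P301S, 20 for its sex interaction, 10398 and 10215 for P301S against WT, and 7540 and 6618 for Dicer with P301S. RLE scaling, the filter of 30 counts, the robust fit and library totals, which were tried for microRNAs only, moved no total by more than 1.5 times, but with library totals 7 microRNAs were higher and 39 lower in P301S males, against 15 and 43. Of 349 mRNA list tests 111 passed at the preset correlation, 19 with an estimated one and 55 by fry; of 50 microRNA list tests 6, 0 and 1. Leaving out each library in turn gave 6 to 1.1e+02 for microRNAs in P301S males, 14 to 62 for their interaction, 54 to 118 for sex in controls, 226 to 342 and 19 to 51 for Dicer KO in males and females. It gave 78 to 868 for age in females, 9 to 32 for sex in WT, 49 to 160 for sex in P301S Dicer KO, 670 to 1052 for P301S Dicer KO against P301S males, 0 to 6 for its sex interaction. It gave 0 to 50 for P301S against WT males, and 236 to 519 and 93 to 407 for Dicer with P301S in males and females. Groups of 2 libraries keep 1 when a library is left out, so their lowest or highest counts rest on the spread of other groups. No named gene or list that passed in the fit reported reversed its direction. Named genes that had not passed changed sign in some settings, with a library left out in 96 of 5334 cases. Some lists that had not passed differed in direction between camera and fry. The seed-match test and its alternatives were not run.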

Other observations

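The test in this part was chosen after the results were seen. Of 360 genes called between Dicer KO and WT males, 188 were also called for age in P301S Dicer KO males, in comparisons that share no library. Of 188 genes called in both, 175 changed in the same direction: 160 rose in both against 11 expected of independent lists, 15 fell in both against 4.34, and 13 were opposite against 15.2. Apoe, Axl, Clec7a and Ms4a7 are among those that rose in both. Across all genes, which are not independent replicates, r was only 0.149. In females 24 of 24 shared genes rose in both, against 0.620 expected, with r of 0.0638. The hypothesis that age moves the genes that Dicer loss moves in the same direction is not settled. The 175 genes of equal direction are above the bound set for it. The bound on opposite genes, at most 0.5 of the expected number, was not met, with 13 against 15.2 expected. Read literally, the outcome written as counting against the hypothesis was therefore reached. All mice in the age comparison are titled P301S Dicer KO, and no mice of another genotype were measured at 3 months. Effects of tau pathology, of Dicer loss over time and of age therefore remain together in this comparison.

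The Y-linked Ddx3y and the X-silencing Xist were seen at low level in P301S Dicer KO libraries of the other sex. Ddx3y was at about 10 CPM in females of that group (7.14 to 12.5) against 1.11 in WT females, and at 2.56 (1.96 to 3.16) in the 2 young libraries (9 against 3 months, log2 change 1.94 ± 0.41, adjusted p = 0.00689, a call lost without either young library). The other Y-linked genes stayed near the floor in the same libraries, Kdm5d at 0.141, Uty at 0.455 and Eif2s3y at 0.533 CPM (0, 0.154 and 0.362 in WT females), too low to show whether they follow Ddx3y. Xist was at 13.8 CPM in males (5.80 to 26.6), 9.79 in young males and 2.90 in WT males. The cause was not tested.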
